A study of Mus musculus with 3 samples.

How the data were processed

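Total RNA sequencing with ribosomal RNA depletion was done on the cytosolic fraction of bone-marrow-derived macrophages from C57BL/6J mice, in 3 libraries of 1 group, per the labels. The labels number the libraries as biological replicates 1, 2 and 3 and give all of them a single donor identifier. The errors therefore measure the spread between these samples, part of which may be technical. The p-values measure something else, those of the list contrasts a difference between genes and those of edgeR a departure from counting noise. The smallest p of an exact sign-flip test over 3 libraries is 0.25, so no test across libraries was made on single values.

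Each library has a gene table and a transcript table with the column layout of RSEM, and a second transcript table with the column layout of kallisto, per the file headers. The authors made all tables on the mouse build mm10 with GENCODE M21, per the text deposited with them, the first tables from alignments to the transcriptome and the second from the reads themselves. The programs, their versions and the strand setting are not given in the sources used here. The gene tables give expected counts, which are estimated reads per gene and need not be whole, as deposited. They also give TPM, scaled by the authors to a fixed sum over all entries of a library. The transcript tables deposited by the authors hold TPM per transcript and the percent of each gene's abundance per transcript. The second tables give estimated counts and TPM per transcript, as deposited, and were summed per gene here.

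The gene table has 81881 entries, of which 55536 are annotated genes, 26248 are tRNAs and 96 are ERCC spike-ins, and 1 is the phage phiX174. All 55536 gene identifiers matched the GENCODE M21 annotation, which gave symbols, classes and mm10 coordinates (1-based). Spike-ins, tRNAs and phiX174 were left out of gene totals, and phiX174 held 0.376%, 0.487% and 0.239% of expected counts in replicates 1, 2 and 3. A gene with 0 counts was given the limit of 3 counts, which for an effective length of 1000 nt is 0.0599, 0.0374 and 0.0361 TPM in replicates 1, 2 and 3. Such limits cover counting error only. TPM divides counts by an effective length, which was about 84.7 nt for the 300 nt 7SL genes, so short RNAs weigh more in TPM than in counts and lower the TPM of all other genes.

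Before the data were examined, 30 gene lists with 447 symbols were fixed, of which 445 matched the annotation. A symbol carried by more than 1 gene took the one with the higher mean TPM. The genes named were also fixed by rule. They were the 4 highest and the 1 lowest of each list, 24 genes chosen in advance, the 10 highest coding genes, the 10 genes above a mean of 10 TPM with the largest SD of log2(TPM + 1), the 5 with the largest ratio between quantifications among those above 10 TPM, and the transcripts of the 5 highest list or chosen genes with at least 2 transcripts at 10% or more. Several markers of other lineages that this rule takes, all below a mean of 1 TPM, are left out of the text. Lists were compared as the difference between their medians of log2(TPM + 1) in each library, given as mean ± SD over 3 libraries, with genes in both lists left out. A two-sided permutation test moved the list labels over genes (100000 resamples, or full enumeration where a list had under 10 genes), with Benjamini-Hochberg adjustment over the 5 contrasts. The spread of a list was the median over its members, at a mean TPM of at least 1, of the SD of log2(TMM-scaled TPM + 1). It was set against 10000 random lists of the same size matched in 20 bins of mean expression.

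Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3, with TMM factors and filterByExpr. The common dispersion gave the biological coefficient of variation, and a fit with dispersion 0 tested each gene against counting noise. A gene differed between quantifications when its TPM differed at least 2-fold in the same direction in every library, with a mean of at least 1 TPM in either. All other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

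The steps were tested on simulated data. With counting noise only and 50 genes changed per fold, the test against counting noise recovered 66% at 1.25-fold, 80% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, and called 6 unchanged genes of 12882 tested. A simulated coefficient of variation of 0.2 came back as 0.197 over 12810 genes. The contrast of 16 against 16 genes gave p under 0.05 in 4% of 200 random draws from 9544 genes and in 100% of draws with a shift of 3 log2 units. Smaller shifts, and lists with genes below 1 TPM, were not simulated, so the power at smaller differences is not known. The list spread passed the 95th percentile in 6% of 50 random lists and in 100% of 20 lists with 3 times the spread, over 9983 genes. The members of these lists were drawn independently, so lists whose members vary together were not covered. The comparison of quantifications recovered 100% of 200 genes planted at 4-fold among 10019, with 0 others called. These simulated tables had no shift common to all genes, whereas the deposited ones had a median log2 ratio of -1.02 over coding genes. The simulation therefore does not cover calls near the 2-fold limit.

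The alternatives were DESeq2 1.42.0 size factors, no count filter, other thresholds and pseudocounts, list means, the second quantification, protein-coding genes only, TPM rescaled to the same sum over protein-coding genes, and leaving out each replicate. Some were added after the data were seen. These were random lists of coding genes only, lists without genes shared by several lists, leaving out each replicate in the list spread, and the rescaled comparison of quantifications. No comparison between groups was possible with 1 group.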

Results

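Transcript levels were measured by total RNA sequencing, with ribosomal RNA depleted, in the cytosolic fraction of mouse bone-marrow-derived macrophages. These are primary macrophages grown from the marrow of the inbred strain C57BL/6J. The cells had been exposed to Lipid A, the part of bacterial lipopolysaccharide that activates the receptor TLR4, at 100 ng/ml for 12 h. Lipid A was then washed out for 12 h, and the cells were stimulated again with 100 ng/ml for 20 min. The series holds 1 group of 3 libraries, which the labels call biological replicates but trace to a single donor identifier. Every error below is therefore a spread between these 3 libraries. No naive, unstimulated or nuclear library was analysed here, so the values are levels after the second stimulation and not responses to it. Expected counts on annotated genes totalled 32055937 in replicate 1, 43616634 in replicate 2 and 47864978 in replicate 3. Levels are given as TPM (transcript abundance scaled to the same sum in each library), mean ± SD over the 3 libraries (n = 3) unless single libraries are named. Coordinates are those of the mouse build mm10.

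The most abundant protein-coding transcripts in these macrophages came from the 2 ferritin subunit genes, which store iron. Fth1 reached 17681 ± 1845 TPM and Ftl1 7559.6 ± 949 TPM. They were followed by the acute-phase gene Saa3 (4947 ± 2090.3 TPM), the actin-binding gene Tmsb4x (4695 ± 958 TPM) and the chemokine gene Ccl5 (4482 ± 1408 TPM). The lysosomal genes Psap (3602 ± 277 TPM) and Ctsd (2701 ± 376 TPM), the MHC class I light chain B2m (3477 ± 1063 TPM), Actb (3466 ± 761 TPM) and lysozyme Lyz2 (3120.4 ± 176 TPM) completed the 10 highest. In all 3 libraries 9544 genes reached 1 TPM, of which 9092 were protein-coding.

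Macrophage genes were abundant and genes of other blood and tissue lineages were close to 0. Of the macrophage identity list, 25 of 26 genes reached 1 TPM in every library, with a list median of 422 ± 71.5 TPM. Besides Lyz2 and Ctsd, the highest members were the cathepsin gene Ctsb (2078 ± 450.1 TPM) and the Fc receptor chain Fcer1g (1361 ± 208 TPM). The fractalkine receptor Cx3cr1 was the exception at 0.0867 ± 0.0153 TPM. The macrophage list lay 8.64 ± 0.19 log2 units (SD, n = 3) above the 68 pooled markers of other lineages, in 3 of 3 libraries, on the log2(TPM + 1) scale. The two-sided permutation test over genes gave p = 1e-05, the smallest value it can give, and an adjusted p of 5e-05 over the 5 list contrasts. Genes are not independent replicates, and across 3 libraries alone an exact sign-flip test could not go below 0.25.

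Among the markers of other lineages, the neutrophil genes S100a9 (6.46 ± 3.16 TPM), S100a8 (4.34 ± 0.868 TPM) and Mmp8 (2.12 ± 0.332 TPM) and the B-cell gene Cd79b (1.70 ± 0.748 TPM) were the 4 that reached 1 TPM in every library. The next neutrophil marker, Ngp, stood at 0.77 ± 0.459 TPM. Ly6g had 0 counts in all 3 libraries, which allows at most 0.146 TPM in the library with the highest limit. Ighm (0.53 ± 0.177 TPM), Vpreb1 (0.237 ± 0.0902) and Igkc (0.207 ± 0.110) were the other B-cell genes named. Median levels were 0.113 ± 0.0569 TPM for the neutrophil list, 0.105 ± 0.0482 TPM for the B-cell list and 0.01 ± 0.0173 TPM for the T and NK cell list, where Lck was highest at 0.0667 ± 0.0252 TPM and Cd3e stood at 0.0267 ± 0.0379. The erythroid list had a median of 0.005 ± 0.00866 TPM, with the globin gene Hba-a2 highest at 0.0467 ± 0.0416 TPM, and the mast cell and basophil list 0.00833 ± 0.0104 TPM, with Kit highest at 0.21 ± 0.0436 TPM. The dendritic cell list had a median of 0.0533 ± 0.0208 TPM, with Ccr7 highest at 0.763 ± 0.225 TPM and Cd209a at 0 counts. The stromal and endothelial list had a median of 0.01 ± 0.01 TPM, with Pecam1 highest at 0.983 ± 0.422 TPM, and the megakaryocyte list 0.0433 ± 0.0247 TPM, with Ppbp highest at 0.19 ± 0.227 TPM.

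**Figure D1:**
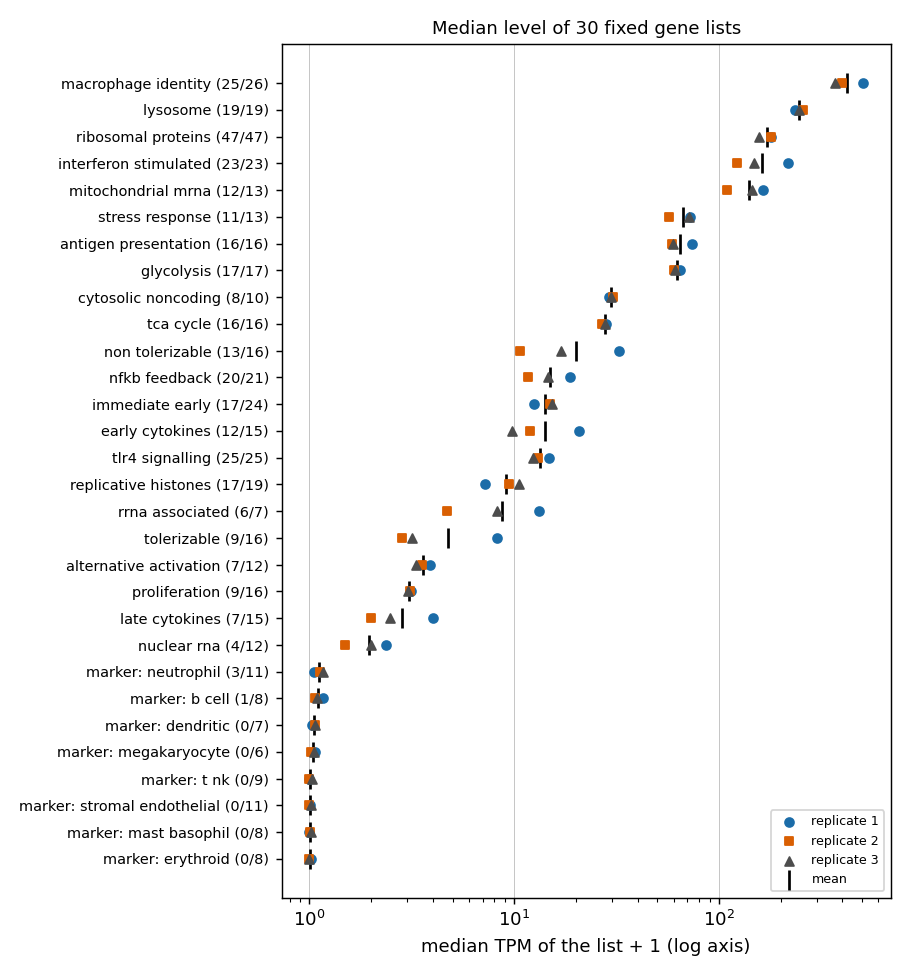
Median TPM plus 1 (log axis) of each of the 30 gene lists in each of the 3 libraries, with the mean as a vertical tick; numbers in brackets are members at 1 TPM or more in every library over members measured. The macrophage identity list (422 TPM) was the highest, and the lists of other lineages lay near 0 TPM.

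Early cytokine genes were present at moderate levels and most late ones at low levels, with a pair of late chemokines as exceptions. The chemokine genes Ccl3 (ENSMUSG00000000982.5; chromosome 11, 83647844 to 83649355) and Ccl4 (ENSMUSG00000018930.3; chromosome 11, 83662584 to 83664683) reached 212 ± 103 TPM and 189.7 ± 110.0 TPM, and Ccl7 and Ccl2 reached 144 ± 88.9 TPM and 129 ± 86.2 TPM. Tnf (ENSMUSG00000024401.14; chromosome 17, 35199381 to 35202007), which encodes the inflammatory cytokine TNF, stood at 83.4 ± 66.9 TPM. Il1b (13.9 ± 9.19 TPM) and Cxcl2 (9.12 ± 6.80 TPM) were lower, and Cxcl1 (1.07 ± 0.879 TPM) was lower still, and Cxcl3 (0.0833 ± 0.0850 TPM) rested on 7, 4 and 1 expected counts in replicates 1, 2 and 3. Among late genes, Ccl5 (ENSMUSG00000035042.2; chromosome 11, 83525778 to 83530518) was the fifth most abundant coding transcript of these cells, and Cxcl10 (ENSMUSG00000034855.13; chromosome 5, 92346638 to 92348889), which encodes an interferon-inducible chemokine, reached 419 ± 383 TPM. The remaining late genes were far lower, with Lipg at 10.5 ± 9.76 TPM, Cxcl9 at 6.24 ± 1.55 TPM, the nitric oxide synthase gene Nos2 at 3.98 ± 4.01 TPM, Il12b at 1.76 ± 1.17 TPM, Ifnb1 at 1.55 ± 1.28 TPM, Il6 at 0.647 ± 0.626 TPM and Csf3 at 0.0233 ± 0.0153 TPM. Replicate 1 raised many of these means by over 1.5 times, counted for means of at least 1 TPM. Without it they were 126 TPM for Ccl4, 93.2 TPM for Ccl7, 79.3 TPM for Ccl2, 44.9 TPM for Tnf, 8.56 TPM for Il1b, 5.49 TPM for Cxcl2, 0.66 TPM for Cxcl1, 198 TPM for Cxcl10, 5.03 TPM for Lipg, 1.67 TPM for Nos2 and 0.81 TPM for Ifnb1. The mean of Il12b was 1.09 TPM without replicate 3. Il6, below a mean of 1 TPM, was also highest in replicate 1 (1.35, 0.44 and 0.15 TPM in replicates 1, 2 and 3).

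Of the early list 12 of 15 members and of the late list 7 of 15 members reached 1 TPM in every library, and the list medians were 13.1 ± 5.80 TPM and 1.83 ± 1.06 TPM. The early list lay 2.31 ± 0.31 log2 units (SD, n = 3) above the late list, in 3 of 3 libraries. The two-sided permutation test over genes gave p = 0.0310 and an adjusted p of 0.0775, which misses 0.05. Without replicate 3 the adjusted p of this permutation test was 0.0385, and over the alternatives it ranged up to 0.233.

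Genes known from earlier work on endotoxin tolerance to lose inducibility after a first exposure (tolerizable) and those known to keep it (non-tolerizable) were compared by level. In the non-tolerizable list 13 of 16 members reached 1 TPM in every library, led by Saa3, by Acod1 (287 ± 169 TPM), which makes the metabolite itaconate, by the mitochondrial superoxide dismutase gene Sod2 (148 ± 40.0 TPM) and by the scavenger receptor gene Marco (102 ± 67.8 TPM). Without replicate 1 the mean of Acod1 was 189.9 TPM, and without replicate 3 that of Marco was 63.0 TPM. Camp was lowest at 0.123 ± 0.0924 TPM. In the tolerizable list 9 of 16 members did so, led by Cxcl10, Ccl3, Ccl4 and Tnf, with Csf3 lowest. The list medians were 3.74 ± 3.03 TPM for tolerizable and 19.1 ± 11.3 TPM for non-tolerizable genes, and without replicate 1 that of tolerizable genes was 1.99 TPM. On the log2 scale the difference was -2.10 ± 0.27 (SD, n = 3), with tolerizable genes lower in 3 of 3 libraries. It did not pass the two-sided permutation test over genes (p = 0.131, adjusted p = 0.164).

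Inhibitors and feedback regulators of NF-kB were present at moderate levels. Nfkbia, which encodes the inhibitor that holds NF-kB in the cytosol, was the highest at 85.0 ± 40.8 TPM. Inpp5d (46.5 ± 3.71 TPM), Birc3 (30.6 ± 11.6 TPM), Tnip1 (30.5 ± 7.19 TPM), the ubiquitin-editing gene Tnfaip3 (23.6 ± 11.1 TPM) and Irak3 (13.5 ± 3.15 TPM), which restrains TLR signalling, were lower. 20 of 21 members reached 1 TPM in every library, and Sigirr, at 0.4 ± 0.0985 TPM, did not. The list median was 14.0 ± 3.56 TPM, and its distance from the early cytokines was 0.14 ± 0.39 log2 units (SD, n = 3), smaller than the spread between libraries (two-sided permutation test over genes, p = 0.764, adjusted p = 0.764). This distance was positive in 1 of 3 libraries (-0.14, -0.03 and 0.58 log2 units in replicates 1, 2 and 3). The sign of its mean turned when list means replaced medians (-0.45) and without replicate 3 (-0.09).

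Immediate-early genes, which are induced within minutes of a stimulus, were led by Atf3 (89.2 ± 28.1 TPM), the mRNA-decay factor gene Zfp36 (85.7 ± 14.4 TPM), Klf6 (83.0 ± 27.4 TPM) and Gadd45b (77.1 ± 28.6 TPM). 17 of 24 members reached 1 TPM in every library, with a list median of 13.2 ± 1.54 TPM. Fos and Egr1 stood at 30.1 ± 16.7 TPM and 8.10 ± 6.11 TPM, and Fosb was lowest at 0.107 ± 0.0451 TPM. Without replicate 3 the mean of Egr1 was 4.65 TPM. The receptor pathway itself was present throughout, since 25 of 25 TLR4 pathway genes reached 1 TPM in every library. Tlr4 stood at 25.5 ± 4.41 TPM, its co-receptor Cd14 at 59.4 ± 6.74 TPM, the adaptor gene Myd88 at 49.9 ± 7.13 TPM, Irf5 at 62.0 ± 13.8 TPM, the kinase gene Mapk14 at 28.9 ± 1.65 TPM and the adaptor gene Tirap, the lowest, at 3.07 ± 0.600 TPM.

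Interferon-stimulated genes were among the most abundant groups. 23 of 23 members reached 1 TPM in every library, and the list median was 162 ± 49.5 TPM. Ifit2 (936 ± 284 TPM), the antiviral gene Rsad2 (824 ± 373 TPM), the transcription factor gene Irf7 (729 ± 182 TPM) and Ifit3 (641 ± 145 TPM) were the highest, and Mx2 was the lowest at 23.1 ± 11.0 TPM. The interferon gene Ifnb1 itself stood at 3.02, 0.78 and 0.84 TPM in replicates 1, 2 and 3.

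**Figure D2:**
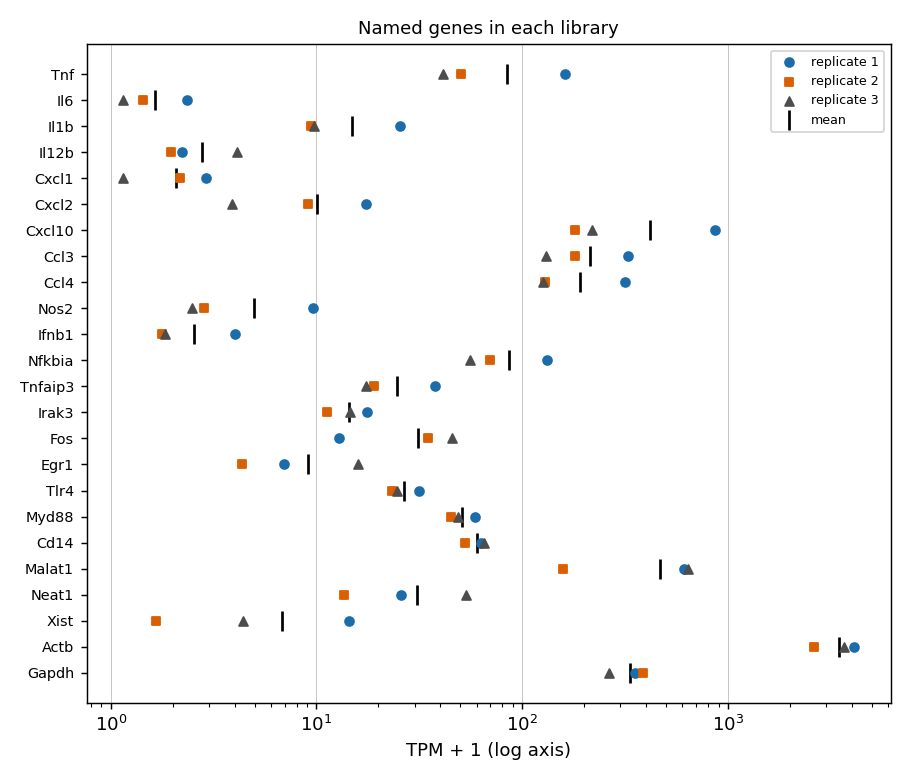
TPM plus 1 (log axis) of 24 genes named before the data were examined, in each of the 3 libraries, with the mean as a vertical tick. Tnf and Cxcl10 were highest in replicate 1 (161 and 861 TPM), Fos in replicate 3 (44.7 TPM), and Malat1 was lowest in replicate 2 (156 TPM).

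Glycolytic genes had a higher median level than genes of the TCA cycle, by a margin that did not pass the test over genes. Gapdh (333 ± 62.8 TPM), Aldoa (159.8 ± 11.9 TPM), Pkm (155 ± 7.01 TPM) and Ldha (116 ± 8.19 TPM) led the glycolytic list, and the glucose transporter gene Slc2a1 was its lowest member at 2.21 ± 0.729 TPM. Sdhb (74.8 ± 2.17 TPM), Mdh2 (54.9 ± 4.46 TPM), Sdhd (47.0 ± 1.71 TPM) and Sdha (46.5 ± 2.64 TPM) led the TCA list, and Suclg2 was lowest at 3.31 ± 0.165 TPM. The list medians were 61.0 ± 2.23 TPM and 26.6 ± 0.580 TPM. The difference of 1.18 ± 0.03 log2 units (SD, n = 3) had the same sign in 3 of 3 libraries. It did not pass the two-sided permutation test over genes (p = 0.105, adjusted p = 0.164).

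Lysosomal and antigen-presentation genes were expressed without exception. 19 of 19 lysosomal genes reached 1 TPM in every library, with a median of 245 ± 11.0 TPM, and the group ran from Psap and Ctsz (882 ± 81.9 TPM) down to the transcription factor gene Tfeb (10.5 ± 0.391 TPM). The Ctsd value is uncertain, because its span overlaps the annotated coding gene Gm49369 on the same strand, at 22.1, 434 and 609 TPM in replicates 1, 2 and 3. 16 of 16 antigen-presentation genes did so with a median of 63.1 ± 8.61 TPM, led after B2m by the class I genes H2-K1 (2096 ± 265 TPM) and H2-D1 (1616 ± 162 TPM) and by Tapbp (321 ± 48.5 TPM), while Ciita, the class II transactivator, stood at 1.51 ± 0.319 TPM. The 47 ribosomal protein genes had a median of 171 ± 13.6 TPM, from Rps24 (686 ± 70.6 TPM), Rplp1 (476 ± 35.6), Rps27 (420.2 ± 114) and Rpl19 (383 ± 41.6) down to Rpl5 (16.3 ± 2.05). The Rpl5 level depends on the quantification. It was 2.54 ± 0.386 TPM in the second, where the list median was 77.9 ± 16.3 TPM. Of the stress genes, 11 of 13 reached 1 TPM in every library, led by the chaperone gene Hspa8 (558 ± 134 TPM), the autophagy receptor gene Sqstm1 (220.4 ± 68.7 TPM), Hspa5 (169 ± 25.8 TPM) and Ddit3 (106 ± 27.0 TPM), with a list median of 66.0 ± 8.46 TPM and Hspb1 lowest at 0.0467 ± 0.0643 TPM.

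Genes of alternative activation were split. Tgfb1 (112 ± 9.22 TPM), Trem2 (108 ± 28.1 TPM), Il1rn (45.8 ± 17.0 TPM) and the mannose receptor gene Mrc1 (19.8 ± 4.21 TPM) were present, 7 of 12 members reached 1 TPM in every library, and the list median was 2.58 ± 0.275 TPM. Retnla had 0 counts in all 3 libraries, which allows at most 0.164 TPM. Cell-cycle genes were low, with a list median of 2.08 ± 0.0527 TPM and 9 of 16 members at 1 TPM or more in every library. Pcna (65.0 ± 4.06 TPM) led Mcm6 (11.7 ± 3.20 TPM), Mcm3 (8.2 ± 2.43 TPM) and Cdk1 (6.04 ± 1.31 TPM), and Ccnb2 stood at 0.2 ± 0.06 TPM. The replicative histone genes had a median of 8.07 ± 1.74 TPM with 17 of 19 members at 1 TPM or more, from Hist1h2bc (65.3 ± 8.31 TPM), Hist1h1c (37.4 ± 3.65), Hist2h2aa1 (34.9 ± 4.30) and Hist1h4b (28.1 ± 6.43) to Hist1h1d (0.91 ± 0.277). The copies of histone genes are near-identical in sequence, so the split of reads among them is uncertain. Mitochondrial mRNAs had a median of 138 ± 27.4 TPM, with mt-Atp8 (870.2 ± 137 TPM), mt-Co1 (705 ± 188 TPM), mt-Nd6 (171 ± 44.2 TPM) and mt-Nd1 (157 ± 18.1 TPM) highest and mt-Co2 at 8.58, 0 and 5.6 TPM in replicates 1, 2 and 3. Nuclear copies of mitochondrial sequence can take part of their reads, which leaves the single mitochondrial genes uncertain. The rank of mt-Atp8 rested on 998, 1233 and 1498 expected counts in replicates 1, 2 and 3, against 59531, 56668 and 73975 for mt-Co1. In the second quantification mt-Atp8 was below mt-Co1, at 187 ± 19.8 and 343 ± 81.0 TPM.

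In the first quantification, short noncoding RNAs held most of the TPM. 7SL, the RNA of the signal recognition particle, which directs new proteins to the endoplasmic reticulum, was annotated as the near-identical genes Rn7s1 (chromosome 12, 69159295 to 69159594) and Rn7s2 (chromosome 12, 69361182 to 69361481). Together they made up 59.2% ± 3.67 of TPM (SD, n = 3) but 8.59% ± 1.33 of expected counts, and the division between them is uncertain. Protein-coding genes made up 29.3% ± 2.99 of TPM and 88.0% ± 1.36 of expected counts. In the second quantification of the same libraries, 7SL took 23.4% ± 4.59 of TPM, protein-coding genes 14.6% ± 2.21, and the 5 pseudogene and miRNA genes Gm12895, Gm12896, Gm24270, Gm24245 and Gm23935 57.3% ± 5.59. The RNase P RNA Rpph1 stood at 34879 ± 14029 TPM and the RNase MRP RNA Rmrp at 12966 ± 8786 TPM, against 14259 ± 4708 and 3542 ± 2219 TPM in the second quantification, and without replicate 3 the mean of Rmrp was 7905 TPM in the first. Both are known mainly from the nucleus and nucleolus, although the list that holds them was fixed as cytosolic. The short RNA Rny3 had 0 counts and no measurable limit in the first quantification and 17.3 ± 4.60 TPM in the second. The list of cytosolic noncoding RNAs had a median of 28.7 ± 0.748 TPM, with 8 of 10 members at 1 TPM or more in every library.

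**Figure D3:**
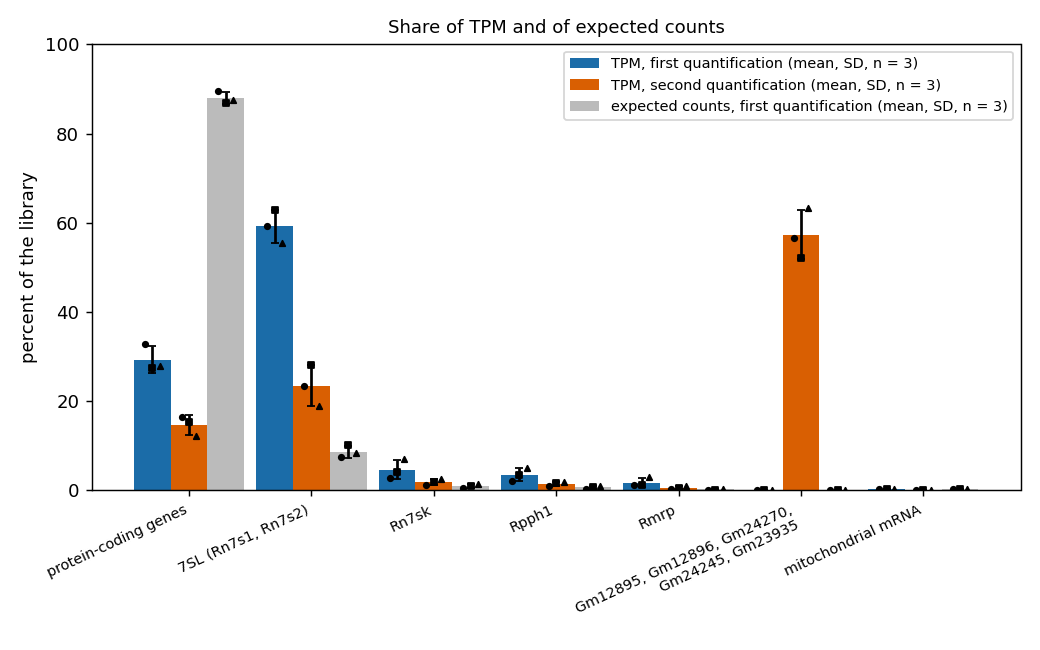
Percent of TPM and percent of expected counts (bars, mean with SD, n = 3; points, single libraries) in protein-coding genes, 4 short noncoding RNAs, 5 pseudogene and miRNA genes and mitochondrial mRNA, with TPM of both quantifications. 7SL took 59.2% of TPM in the first and 23.4% in the second quantification, and protein-coding genes took 88.0% of expected counts.

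RNAs known to reside in the nucleus were present in this cytosolic fraction and differed between libraries. The long noncoding RNA Malat1 (ENSMUSG00000092341.3; chromosome 19, 5795690 to 5802672) stood at 612, 156 and 637 TPM in replicates 1, 2 and 3, Neat1 at 24.8, 12.7 and 52.4 TPM and Xist at 13.4, 0.66 and 3.42 TPM. Dleu2 (8.13 ± 1.13 TPM) varied less, and Miat had 0 counts. Rn7sk, the RNA of the 7SK particle, was far above them at 27429.5, 40201 and 69035 TPM. The list had 4 of 12 members at 1 TPM or more in every library and a median of 0.957 ± 0.439 TPM. Genes that collect ribosomal RNA reads also differed, most widely Gm26917 at 643, 16.2 and 69.3 TPM. Gm42418 stood at 205, 29.1 and 93.9 TPM, CT010467.1 at 218, 33.3 and 68.8 TPM and mt-Rnr1 at 12.3, 3.67 and 7.25 TPM. 6 of 7 measured members of that list reached 1 TPM in every library, with a median of 7.73 ± 4.31 TPM and AY036118 at 0 counts.

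Cytokine genes differed between the 3 libraries more than most genes of like level. Tnf stood at 161, 49.6 and 40.1 TPM in replicates 1, 2 and 3, Cxcl10 at 861, 179 and 218 TPM, Ccl3 at 328, 179 and 129.5 TPM, Ccl4 at 317, 127 and 125 TPM, Il1b at 24.5, 8.39 and 8.73 TPM, Cxcl2 at 16.4, 8.08 and 2.89 TPM and Nos2 at 8.61, 1.85 and 1.48 TPM. After TMM scaling, 14 of 14 early cytokines, 8 of 10 late cytokines, 22 of 23 interferon-stimulated genes and 18 of 20 NF-kB feedback genes were highest in replicate 1. Other genes were ordered differently, among them the late cytokine gene Il12b at 1.21, 0.97 and 3.11 TPM. Fos stood at 11.9, 33.8 and 44.7 TPM and Egr1 at 5.97, 3.33 and 14.99 TPM, and Marco at 73.3, 52.7 and 179 TPM.

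Of 23 lists with at least 3 members at a mean of 1 TPM, 14 had a median SD at or above the 95th percentile of 10000 random lists matched on expression. Early cytokines (median SD 0.70 log2 units, percentile 100), tolerizable genes (0.73, 100), non-tolerizable genes (0.67, 100), late cytokines (0.59, 100) and immediate-early genes (0.38, 100) were among them. NF-kB feedback genes, interferon-stimulated genes, nuclear RNAs, ribosomal RNA-associated genes, replicative histones, proliferation, alternative activation, stress response and mitochondrial mRNA were the others. Every tolerizable gene is also in the early or late cytokine list, so the spread of that list is not a separate result. Genes of the random lists were drawn independently, whereas the members of a fixed list may vary together. A percentile is therefore a description and not a test. The TCA cycle had the lowest percentile (2.18), then antigen presentation (13.2), lysosome (30.8), cytosolic noncoding RNAs (41.7) and the TLR4 pathway (53.0). Ribosomal proteins (73.0), macrophage identity (83.1), glycolysis (90.4) and neutrophil markers (92.6) lay between. Which list was lowest depended on the setting. Ribosomal proteins were lowest with TPM as deposited (0.06, against 0.46 for the TCA cycle) and without replicate 2 (0.14 against 7.28). The lysosome list was lowest in the second quantification (0.92 against 3.65), antigen presentation without replicate 1 (12.7 against 23.8) and macrophage identity without replicate 3 (1.55 against 7.83). Without replicate 1 the number of lists at or above the 95th percentile was 8, and early cytokines (83.8), late cytokines (82.0), tolerizable genes (94.3), NF-kB feedback genes (92.8), interferon-stimulated genes (78.9), replicative histones (82.6), stress response (94.1) and mitochondrial mRNA (83.8) were below it. Macrophage identity (96.1) and ribosomal proteins (95.4) were then above it. Without replicate 2, alternative activation (69.5) and mitochondrial mRNA (88.8) were below it and neutrophil markers (96.6) above it. Without replicate 3, proliferation (25.2) and stress response (58.9) were below it. In the second quantification, mitochondrial mRNA (61.4) and stress response (93.1) were below it, as was alternative activation (86.6) with genes of several lists left out. Immediate-early genes (99.5), non-tolerizable genes (100), nuclear RNAs (100) and ribosomal RNA-associated genes (100) were above it without replicate 1, and also without replicate 2 or 3.

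The 10 genes above a mean of 10 TPM with the largest SD were mostly small nuclear and nucleolar RNAs within other genes. The snRNA gene Gm24497 stood at 322, 0.02 and 1376 TPM in replicates 1, 2 and 3 and lies within D230017M19Rik. The snoRNA genes Gm26447 (606), Gm25791 (83.5), Gm26079 (40.6) and Gm26165 (39.4) had those TPM values in replicate 1 and 0 TPM in replicates 2 and 3. They rested on 33.0, 7.97, 2.97 and 4 expected counts in replicate 1, and Gm26447 had 2 and 2.98 counts in replicates 2 and 3. A count of 0 allows up to 22.2 and 27.1 TPM for Gm25791 and 20.8 and 25.4 TPM for Gm26165 in those replicates, and 29.4 TPM for Gm26079 in replicate 2, so the differences of these 3 genes rest on few counts. The 4 snoRNA genes lie within Eif4a2, Taf1d, Ep400 and Snx5. Gm26397, within Tomm20, stood at 51.0, 0 and 22.6 TPM from 4, 0 and 2 counts. Rnu3b4 and Rnu3b2, within Tex14, had the same values as each other, 49.7, 21.2 and 0 TPM. The pseudogene Gm14303 stood at 163, 2.14 and 0 TPM, and Gm37376, antisense to Malat1, at 0, 0 and 37.4 TPM. Reads of each such gene and its overlapping host cannot be separated with certainty.

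Across all genes the biological coefficient of variation between the libraries was 19.0% (edgeR common dispersion). Of 12372 genes kept by the count filter, 8802 (71.1%) varied beyond counting noise at an adjusted p of 0.05 (edgeR fit with dispersion 0, deviance test with Benjamini-Hochberg adjustment). Between replicates 1 and 2, 6340 of 12296 genes differed beyond counting noise, between replicates 1 and 3, 6822 of 12779, and between replicates 2 and 3, 6564 of 12556. Libraries prepared separately are expected to differ by more than counting noise, so these counts do not show that the replicates are independent. Over the 9544 detected genes, Pearson's r of log2(TPM + 1) between pairs of libraries was 0.980, 0.982 and 0.984. This is a correlation across genes, which are not independent replicates.

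Each library was also quantified a second time by the authors, and the genes that differed most between both tables were short or repeated sequences. The processed pseudogenes Gm12895 (chromosome 4, 122455210 to 122455435) and Gm12896 (chromosome 4, 122122847 to 122123072) had 0 expected counts in the first quantification and 131485 ± 17961 TPM each in the second. The miRNA genes Gm23935, Gm24270 and Gm24245 had 0 expected counts in the first and 103474 ± 11746 TPM each in the second. Among protein-coding genes, the median log2 ratio of the second quantification over the first was -1.02 ± 0.16 (SD, n = 3). In total, 995 of 10308 genes differed at least 2-fold in the same direction in every library, 277 higher and 718 lower in the second. Without replicate 2 the number was 5067, since the median ratio of coding genes in replicates 1 and 3 (-0.99 and -1.19 log2 units) lay near or beyond the 2-fold limit. After rescaling both tables to protein-coding genes, 1219 genes were higher and 274 lower in the second, of 13893 genes compared.

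The most abundant transcript was the same in both quantifications for 3477 of 3844 genes with at least 2 transcripts and a mean of 10 TPM (90.5%). Among named genes, Psap was divided between Psap-202 (59.4% ± 2.57, n = 3) and Psap-203 (37.8% ± 2.99). Ctsd was divided between Ctsd-202 (68.1% ± 5.52) and Ctsd-201 (31.7% ± 5.59), whereas the second quantification placed 98.5% ± 1.02 on Ctsd-202. For H2-K1 the retained-intron transcript H2-K1-215 (43.7% ± 1.59) was above the coding H2-K1-201 (40.8% ± 0.973) in 3 of 3 libraries. The second quantification gave the other order, with 35.4% ± 2.35 on H2-K1-215 and 49.1% ± 1.85 on H2-K1-201. Ctsb-201 held 86.9% ± 10.4 and the retained-intron transcript Ctsb-202 12.9% ± 10.4, against 63.3% ± 9.88 and 36.6% ± 9.88 in the second quantification. Irf7 was spread over Irf7-201 (49.0% ± 1.90), Irf7-203 (26.6% ± 1.85) and Irf7-202 (15.5% ± 0.336), against 62.6% ± 1.15, 13.9% ± 0.512 and 10.9% ± 0.220 in the second quantification.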

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

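Reads of the bacteriophage phiX174, whose DNA is commonly added to sequencing runs as a control, were present in each library although they are part of no comparison above. They numbered 120975 expected counts in replicate 1, 213333 in replicate 2 and 114572 in replicate 3, against a limit of 3 counts. These were 0.376% (95% exact Clopper-Pearson interval 0.374 to 0.378), 0.487% (0.485 to 0.489) and 0.239% (0.237 to 0.240) of expected counts. The intervals cover counting error only. These shares were computed only after the counts had been seen. The ERCC spike-ins had 0 expected counts in each library, and the tRNAs had 1, 0 and 1. Outlying libraries were not tested for, since the group has 3.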

How the results depend on the processing

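The alternatives were chosen before the data were examined, except for the list spread on coding genes, without shared genes or without single replicates, and the quantifications after rescaling. Macrophage identity over other lineages kept its direction and stayed past the threshold under every alternative run (7.48 to 11.76 log2 units). Tolerizable against non-tolerizable genes (-2.43 to -1.58) and glycolysis over TCA cycle (0.79 to 1.21) kept their direction and passed the threshold under none. Early over late cytokines kept its direction (1.67 to 2.83 over all alternatives, and 2.17 to 2.48 leaving out single replicates). It passed the threshold only without replicate 3, with an adjusted p of 0.0385 by permutation against a range of 0.0385 to 0.233 over all alternatives. NF-kB feedback genes over early cytokines, called under no setting, reversed with list means (-0.45) and ran from -0.085 (without replicate 3) to 0.28 leaving out single replicates. The cause was not tested for either.

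The number of genes detected (8376 to 12387), the coefficient of variation (16.7% to 23.2%), genes beyond counting noise (6340 to 10759) and the share with the same major transcript (89.7% to 90.6%) stayed within 1.5 times the reported value. The number of lists past the 95th percentile of spread ran from 8 (without replicate 1) to 14 (TPM as deposited, and random lists of coding genes). It was 13 without replicate 2, 12 without replicate 3 and in the second quantification, and 12 of 22 without shared genes. Genes differing between quantifications numbered 432 at 4-fold, 370 at a mean of 10 TPM and 552 among coding genes, where fewer genes qualify by construction. They numbered 1493 after rescaling (1219 higher and 274 lower in the second), and 1027 to 5067 leaving out single replicates, highest without replicate 2. Rescaling, which multiplies all genes of a library alike, moved 152 of 161 named-gene levels (the other 9 are at 0 TPM) and 30 of 30 list medians beyond 1 SD, and the second quantification moved 103 and 19. Leaving out 1 of 3 replicates cannot move a mean by 1 SD, so folds were counted for values of at least 1 TPM. Over 1.5-fold moved 17 of 111 gene levels without replicate 1 (most for Gm26917, to 42.8 TPM, and among them Cxcl10 and Tnf, to 198 and 44.9 TPM), 0 without replicate 2 and 5 without replicate 3 (Egr1, Rmrp, Il12b, Marco and Neat1). Of 21 list medians only that of tolerizable genes did so, to 1.99 TPM without replicate 1. Depth limits long genes at the lowest TPM and short RNAs at far higher values, such as Gm26079 with 40.6 TPM from 2.97 counts.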

Other observations

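The tests of retained-intron transcripts and of the median ratio after rescaling were chosen before their results were seen, and the other tests after.

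Several coding genes outside the lists also differed between the libraries. They were chosen after their values were seen, as the coding genes above a mean of 10 TPM with the largest SD. The stem-cell antigen gene Ly6a stood at 247, 106 and 52.7 TPM in replicates 1, 2 and 3, the G-protein regulator gene Rgs1 at 144, 65.6 and 28.1 TPM, the interferon-inducible GTPase gene Tgtp1 at 38.6, 7.48 and 11.9 TPM, Slfn4 at 19.1, 3.03 and 10.1 TPM, Ifit1bl1 at 232, 67.3 and 57.4 TPM and the transcription factor gene Cebpb at 47.5, 14.0 and 14.3 TPM. Slc13a3, a dicarboxylate transporter gene, was ordered differently at 19.5, 8.86 and 36.6 TPM. Gm49369, which overlaps Ifitm10 and Ctsd on the same strand, stood at 22.1, 434 and 609 TPM, and Gm20721 at 1.78, 27.5 and 2.71 TPM. These 2 genes depend on how reads were assigned, with means of 45.2 and 0.258 TPM in the second quantification against 355 and 10.7 TPM in the first. Xist stood at 13.4, 0.66 and 3.42 TPM, and the Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y had 0 expected counts in the first quantification.

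No biological explanation was tested, because the series has 1 group.

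The first pattern is that 67 inflammatory genes (early and late cytokines, NF-kB feedback and interferon-stimulated genes with a mean of at least 1 TPM) differed together between libraries, with median log2 deviations of 0.44, -0.25 and -0.21 in replicates 1, 2 and 3 after TMM scaling. A library-wide scale is argued against, since the range of 0.69 remained after scaling against a 95th percentile of 0.11 in matched random sets. Retained-intron transcripts did hold their highest share of coding-gene TPM in replicate 1, in both quantifications (3.61%, against 2.98% and 3.21%, in the first), but the range was still 0.66 over transcripts typed as coding. The 3 neutrophil markers at a mean of 1 TPM or more (S100a8, S100a9 and Mmp8) summed to 9.16 TPM after scaling in replicate 1, below 12.5 and 17.3 TPM in replicates 2 and 3 (counting errors 0.717, 0.700 and 0.828 TPM). This argues only weakly against neutrophils, since counting errors leave out the spread between libraries. S100a9 rested on 54, 129 and 241 expected counts in replicates 1, 2 and 3. Cells of the other lineages listed stay open, because only 1 of their 57 markers reached a mean of 1 TPM, and the sum of 5.48 TPM in replicate 1 lay between 5.18 and 8.23 TPM in replicates 2 and 3. Carry-over of nuclear RNA cannot be told apart from a difference in the cells, because nuclear RNAs went both ways. The set was 0.61 log2 units higher in replicate 1 than in replicate 3, in 63 of 67 genes. So were 2 of 6 nuclear RNAs at a mean of 1 TPM or more, Xist (12.5 and 3.47 TPM after scaling) and Firre (1.54 and 1.26 TPM). The ribosomal RNA-associated genes were higher in replicate 1 in 6 of 6. They include the mitochondrial genes mt-Rnr1 and mt-Rnr2, so they are no measure of nuclear RNA. How completely ribosomal RNA was depleted in each library was not tested. The snoRNA genes, at 0.302% of TPM in replicate 1 and 0.122% in replicate 3, and the share of retained-intron transcripts were also higher in replicate 1, whereas snRNA genes (0.606% and 1.01%) and scaRNA genes (0.0470% and 0.0620%) were higher in replicate 3. The other 4 nuclear RNAs were higher in replicate 3, Malat1 (571 and 647 TPM in replicates 1 and 3), Neat1 (23.2 and 53.2 TPM), Dleu2 (7.98 and 9.11 TPM) and Rn7sk (25585 and 70029 TPM). A difference between the cultures also stays open as untested.

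The second pattern is that listed nuclear long noncoding RNAs were lowest in replicate 2, in 5 of 5 at a mean of 1 TPM or more (Malat1, Neat1, Dleu2, Xist and Firre). This count describes the pattern and tests no explanation. Carry-over of nuclear RNA may contribute, as 3 of 3 classes of small nuclear RNA (snRNA, snoRNA and scaRNA) and the share of retained-intron transcripts (2.98%, in both quantifications the lowest) were also lowest there, each by chance in 1 of 3 cases. Other mainly nuclear RNAs cannot decide on carry-over, because they went both ways. Replicate 2 was above replicate 1 by 0.55 log2 units for Rn7sk and by a median of 0.47 for Rpph1 and Rmrp (0.71 and 0.22). It was below replicate 3 for each of them. The values in replicates 2 and 3 were 40201 and 69035 TPM for Rn7sk, 34486 and 49101 for Rpph1, and 8503 and 23087 for Rmrp. Lower depth is argued against, as replicate 2 had 43.6 M expected counts on genes and replicate 1 had 32.1 M, and a difference in the cells stays open.

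The third pattern is that protein-coding TPM was lower in the second quantification by about 1 log2 unit. Most coding genes shared this shift, since the 25th and 75th percentiles of the log2 ratio over 9083 coding genes lay 0.166 apart (-1.06 and -0.898), against a median of -1.02. It cannot explain 6 of 4074 coding genes at a mean of 10 TPM or more in either table, which were at least 2-fold higher in the second quantification in every library. TPM taken up by 7SL, Rn7sk, Rpph1 and Rmrp is argued against as the source of the shift, because their share of TPM was 27.0% in the second and 68.6% in the first (second minus first, -41.5 ± 3.90 percentage points, SD, n = 3; lower in 3 of 3 libraries). The 5 pseudogene and miRNA genes held 57.3% of TPM in the second and 0 in the first, while protein-coding genes held 14.6% and 29.3%. TPM has a fixed sum, so a gain on these 5 genes lowers the share left to all others. Why the tables assigned reads to these genes differently was not tested. The median log2 ratio of -0.00346 ± 0.0163 (SD, n = 3) after rescaling to coding genes is no evidence on the source of the shift, because the rescaling itself brings it close to 0. Which of the tables is nearer to the true abundance of the short RNAs was not tested.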
